A study of Homo sapiens with 6 samples.

How the data were processed

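RNA sequencing was done on 6 libraries of HCT116 and SW620 cells, 1 pLKO control and 2 TEAD4 knockdown libraries per line. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with the TruSeq RNA kit, which selects polyadenylated RNA and keeps no strand, and cells were grown in DMEM with serum. Without strand, reads of a gene and of an antisense gene on the same locus cannot be told apart.

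The authors deposited 1 table per line with 26364 features. Each table holds a signal per library, the normalized count, which the authors made by dividing reads per gene by 1 size factor per library within that table, as the deposited values show. Multiplying by these size factors gave whole reads for 100% of the values within a tolerance of 1e-06. The authors' mean signal, their log2 fold changes with standard errors, the score of their test (log2 fold change divided by its standard error), and their p-value and adjusted p-value per gene stand in the same tables, per the file headers. The authors' log2 fold changes were smaller in size than the log2 ratios of the normalized counts for 99.97% of features in HCT116 and 99.98% in SW620, so they are shrunken, as DESeq2 does. Bowtie 0.12.2 and hg18 are named in the submitters' processing notes, which give them no role. The gene counter and the gene annotation are not given in the sources used here. Shared reads of near-identical genes (histones, ribosomal proteins with their pseudogenes, GOLGA8 genes) could therefore be split in ways that are not known.

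Of the features, 28 carried date-like names (26 distinct names), the mark of spreadsheet conversion of gene symbols, and were left out. They took from 0.232% to 0.262% of a library's reads. This left 26336 genes, of which 25172 symbols (95.6%) matched a current or older symbol of the reference annotation. The reference served for names, for GC content and transcript length (92.9% of genes) and for the position of TEAD4 on GRCh38.

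The libraries held from 15778571 to 18859715 reads on named genes. The 10 genes with most reads took from 3.95% to 6.24% of them. The knockdown libraries of a line were not duplicates, since their counts differed by far more than sampling noise (chi-square per degree of freedom 109.9 in HCT116 and 30.9 in SW620). Columns of the tables give the knockdown libraries the numbers 1 and 2 and not the letters A and B of the labels, so the letters are not used.

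The design had been fixed for raw counts, with the edgeR quasi-likelihood test, and for normalized values with limma. Since the tables hold normalized values, limma was used (eBayes with trend, on log2(normalized count + 1), two-sided). Fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 normalized count over the 6 libraries were tested (18743 genes), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Both lines together were fitted with line and knockdown as terms (3 residual degrees of freedom). Each line and the difference between lines were taken from a model of 4 groups with 2 residual degrees of freedom, in which the lone control of a line is assumed to vary like the knockdown pairs. This model shares 1 spread over both lines, though the knockdown pair differed more in HCT116. Standard errors can thus be too small for HCT116 and too large for SW620. The smallest adjusted p over all genes was 0.356 for both lines, 0.828 for HCT116 and 1 for SW620 and for the difference. The median standard error of a log2 fold change was 0.37, 0.54, 0.54 and 0.77 in that order.

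Of gene lists, 24 were fixed, with 464 symbols of which 454 were found. They were the YAP/TAZ-TEAD targets, Hippo pathway and TEAD family, mesenchymal markers, epithelial junction and keratin genes, Wnt targets, G2/M and mitosis, DNA replication and G1/S, p53 targets, interferon-stimulated genes, and NF-kB and inflammatory genes. Further lists were AP-1 and immediate early genes, unfolded protein response and ATF4 targets, cholesterol biosynthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, enterocyte and colon differentiation, extracellular matrix and adhesion, and apoptosis regulators. Fibroblast, leukocyte and endothelial markers stood for other cell types, and histone and mitochondrially encoded genes for RNA selection. The mitochondrially encoded list was not tested, since 0 of its 9 members were found, which leaves 23 lists. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the lists of a comparison. With the estimated correlation, and with fry, 0 lists passed in any comparison. Members were also adjusted over the list alone.

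The genes named in the text follow a rule. They are TEAD4 in every library, and the genes past the threshold by size of change or, where none passed, the 5 with the smallest unadjusted p. From each list they are up to 4 members with the smallest p in the comparison reported, and in every comparison TEAD1, TEAD2, TEAD3, YAP1, WWTR1, CYR61, CTGF, ANKRD1, VIM and CDH1. The text gives a part of the genes so named, and that part was chosen after the values were seen. One result is not reported here. Genes called by DESeq2 or in the authors' deposited table, and the genes of the other observations, were named after their values were seen. The tests, samples, thresholds, gene lists, naming rule and a set of other settings were fixed before the data were examined.

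The other settings fixed then were quantile normalization, centring libraries on their median, no filter on low values, a mean of at least 5 normalized counts, limma without trend, a pseudocount of 0.1, the libraries of 1 line alone and leaving out each library. The edgeR quasi-likelihood test (TMM) and the DESeq2 Wald test on the recovered reads were chosen after seeing the data, as were the removal of the trend on GC content and length, the blocks on column number and the overlap of each line's libraries alone at unadjusted p. Overlap was tested with Fisher's exact test, and the correlation of folds against a shared control was set beside 100 simulations of unchanged libraries. For genes with few reads, ratios carry 95% exact counting intervals. The authors' own comparisons are quoted as deposited.

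The limma scripts were tested on simulated counts for 18743 genes with 200 changed genes, 50 at each fold, and a median dispersion of 0.106 as estimated from these libraries. For both lines, 0% of genes changed 1.5-fold, 6% of 2-fold, 86% of 4-fold and 98% of 8-fold were recovered, with 0 calls among unchanged genes. On the same data for both lines, edgeR and DESeq2 each recovered 98% of 4-fold changes, with 3 calls among unchanged genes in edgeR and 20 in DESeq2. DESeq2 made 7 such calls for HCT116 and 6 for SW620, and edgeR 2 and 3. For single lines edgeR recovered 56% of 4-fold and 96% of 8-fold changes in HCT116, and 54% and 94% in SW620. DESeq2 recovered 74% and 66% of 4-fold changes in the same order of lines. The simulation gave genes of like level the same dispersion, with no scatter between them, and each gene the same change in both lines, so its recovery can be too high. In the real libraries edgeR and limma called 0 genes, although TEAD4 stood at 19.2% to 23.5% of its control. The 0 calls of edgeR, and those of limma for both lines, therefore do not argue against large changes. For HCT116 and for SW620 alone, limma recovered 0% at every fold, so a count of 0 in limma for 1 line says nothing on the presence of changes. Recovery for the difference was not simulated, since both lines were given the same changes. With a dispersion of 0.01, 90% of 4-fold changes were recovered in each line. With the dispersion estimated from these libraries, a raised list of 24 members gave a camera p of 1.8e-09 for both lines. Its members were simulated as independent, while the real DNA replication list had an estimated correlation of 0.312 for both lines. This p therefore does not show how camera treats lists whose members move together. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.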

Results

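RNA was sequenced from 2 human colorectal cancer cell lines, HCT116, derived from a primary colon carcinoma, and SW620, derived from a lymph node metastasis of a colon carcinoma. In each line TEAD4 was knocked down with short hairpin RNA. TEAD4 is a TEA domain transcription factor that binds DNA together with the Hippo pathway effectors YAP and TAZ. Each line had 1 control library, carrying the lentiviral hairpin vector pLKO, and 2 TEAD4 knockdown libraries, which makes 6 libraries in all. The series asks which genes depend on TEAD4 in colorectal cancer cells. HCT116 libraries held 15778571 reads on named genes in the control and 16045160 and 17089096 in knockdown libraries 1 and 2, numbered as in the deposited columns. SW620 libraries held 18158268, 18859715 and 16984496 in the same order. EEF1A1, a translation elongation factor, took the largest share of reads in every library, from 0.990% to 1.54%. The labels do not say whether the knockdown libraries of a line came from separate cultures or separate hairpins. The gene tests of 1 line and of the difference thus measure only the spread between these libraries, technical or not. In the model of both lines, the spread also holds any difference between the lines in their response. Camera and Fisher's exact test set genes against other genes, so their p-values do not measure that spread alone.

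TEAD4 itself (chromosome 12, 2959330 to 3040673, plus strand, GRCh38) was low in every knockdown library. In HCT116 it stood at 355 normalized counts in the control and at 68.2 and 68.6 in the knockdown libraries, 19.2% and 19.3% of the control. In SW620 it stood at 1140.4 in the control and at 268 and 234 in the knockdown libraries, 23.5% and 20.5% of the control. These levels rest on 349, 75 and 64 reads in HCT116 and on 1168, 271 and 228 reads in SW620. The tables of the lines were normalized separately, here and for every other level set across the lines. Across both lines the log2 fold change was -2.27 ± 0.25 (SE), with an unadjusted limma p of 1.9e-05. The limma adjusted p was 0.356 over all genes and 4.0e-04 adjusted over the list alone, the Hippo pathway and TEAD family list. DESeq2 gave TEAD4 an adjusted p of 5.8e-14. The authors' deposited table gave a shrunken log2 fold change of -1.51 in HCT116 (adjusted p = 0.432) and of -1.31 in SW620 (adjusted p = 1.92e-05).

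With both lines in 1 model, the genes with the smallest p-values were lower with TEAD4 knockdown in all 4 knockdown libraries. They were TEAD4 and 4 others. FLNC, the actin crosslinker filamin C, had a log2 fold change of -1.84 ± 0.25 (SE), and SLC4A8, a sodium-dependent bicarbonate transporter, one of -2.38 ± 0.39. HIST1H1C, a linker histone, stood at -1.49 ± 0.24 and TGM2, tissue transglutaminase, at -1.44 ± 0.25. As a group, genes of DNA replication and the G1/S transition were higher with knockdown (camera adjusted p = 2.9e-07). Histone genes were lower (camera adjusted p = 0.0158). Neither list passed with an estimated correlation (camera adjusted p = 0.646 for each), a setting that could hardly call a list here.

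**Figure D1:**
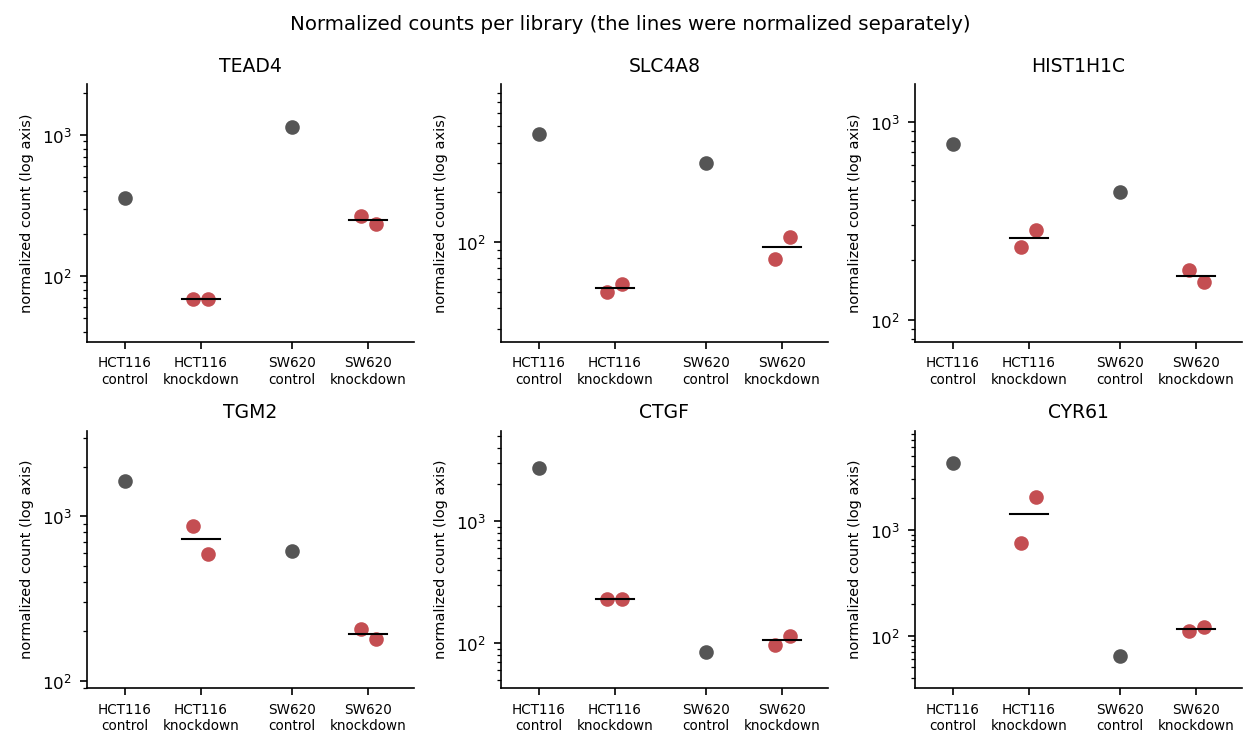
Normalized counts (log axis) of TEAD4, SLC4A8, HIST1H1C, TGM2, CTGF and CYR61 in each library, with grey points for the 2 pLKO controls, red points for the 4 TEAD4 knockdown libraries and a black line at the mean of a line's knockdown libraries. TEAD4, SLC4A8, HIST1H1C and TGM2 lie below the control in both lines, and CTGF goes from 2736 to 228 and 227 in HCT116 and from 84.9 to 96.9 and 115 in SW620.

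None of these genes passed the test over all genes. With limma, 0 of 18743 genes had an adjusted p under 0.05, and the smallest was 0.356. TEAD4 itself missed the threshold, so this count does not show that large changes were absent. An unadjusted p under 0.05 was reached by 831 genes, 324 higher and 507 lower, where chance alone gives 937. The quasi-likelihood test of edgeR called 0 genes, and DESeq2 called 15, of which 1 was higher and 14 lower. In a single simulated data set for both lines, with 200 changed genes, DESeq2 made 20 calls among unchanged genes, edgeR 3 and limma 0. There DESeq2 also recovered 98% of 4-fold and 100% of 8-fold changes. Under this threshold false calls grow with the number of true ones, so these counts do not tell how many of the 15 are false. FLNC (DESeq2 adjusted p = 9.6e-06), SLC4A8 (3.7e-05), HIST1H1C (3.7e-05) and TGM2 (0.00202) were among the DESeq2 calls. The only DESeq2 call that was higher, named after its value was seen, was PVRL1, a nectin cell adhesion molecule, with a DESeq2 log2 fold change of 1.23 and an adjusted p of 0.0489.

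The DNA replication and G1/S list held 24 measured members, of which 21 had a positive and 3 a negative log2 fold change, with a median of 0.34. The median against the line's own control was 0.24 and 0.69 in the HCT116 knockdown libraries and 0.20 and 0.27 in the SW620 ones. Camera gave the list an adjusted p of 2.9e-07, and the camera adjusted p was 0.646 with an estimated correlation. Among its members were GINS1, of the GINS helicase complex (0.69 ± 0.22), and the MCM helicase subunits MCM4 (0.62 ± 0.21), MCM5 (0.67 ± 0.25) and MCM2 (0.53 ± 0.20). Of the members, 6 had an unadjusted p under 0.05, all higher, and 0 passed over all genes or adjusted over the list alone. Without the HCT116 control the list's median was 0.22 (camera adjusted p = 0.00467).

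The histone list had 7 of 9 measured members lower, with a median log2 fold change of -0.29 and a camera adjusted p of 0.0158. The camera adjusted p was 0.646 with an estimated correlation. HIST1H1C passed adjusted over the list alone (limma adjusted p = 0.00252), and HIST1H2BC stood at -1.56 ± 0.57 and HIST1H2AC at -0.98 ± 0.46. Histone genes belong to families of near-identical copies, so their counts are uncertain, and the list also serves as a sign of how RNA was selected. Its camera adjusted p was 0.0534 without the HCT116 control (median -0.35), 0.139 without the SW620 control (-0.32) and 0.0580 without SW620 knockdown library 2 (-0.26), and the median was -0.48 without HCT116 knockdown library 1 (0.0445).

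The YAP/TAZ-TEAD target list did not pass (camera adjusted p = 0.159), with 17 of 22 members lower and a median log2 fold change of -0.42. Its median against the line's own control was 0 and -0.16 in the HCT116 knockdown libraries and 0.07 and -0.14 in the SW620 ones. A median of that size was thus not reached in any single library. CTGF and CYR61, secreted matricellular proteins, stood at -1.64 ± 0.74 and -0.46 ± 0.61 over both lines, and ANKRD1, an ankyrin repeat protein, at -0.78 ± 0.70. Among other members, CCDC80 was at -1.50 ± 0.53, F3, the coagulation initiator tissue factor, at 0.64 ± 0.26 and PTPN14 at 0.47 ± 0.22. The Hippo pathway and TEAD family list had a camera adjusted p of 0.266. Its median (0.02) was positive while its mean (-0.16) and the test pointed lower, and 1 of 21 members, TEAD4, passed adjusted over the list alone. NF2, the tumour suppressor merlin, stood at 0.79 ± 0.25, AMOT at -0.56 ± 0.22 and FRMD6 at -0.56 ± 0.24. The other TEAD genes and the effectors showed no common direction in the 4 knockdown libraries, except for the sign of TEAD1 (-0.51 ± 0.35). TEAD1 stood at -1.07 and -0.05 in HCT116 knockdown libraries 1 and 2 and at -0.01 and -0.92 in the SW620 ones. It was thus near the control in 1 library of each line. TEAD2 was at -0.18 ± 0.52, TEAD3 at 0.09 ± 0.25, YAP1 at 0.10 ± 0.49 and WWTR1, which encodes TAZ, at -0.30 ± 0.44.

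Mesenchymal markers (camera adjusted p = 0.246) had 16 of 20 members lower, with a median of -0.34. FN1, fibronectin, stood at -0.88 ± 0.34, VIM, vimentin, at -0.50 ± 0.48 and FSCN1, the actin bundler fascin, at 0.74 ± 0.24. Epithelial junction and keratin genes (camera adjusted p = 0.793) had a median of 0.02, and CDH1, E-cadherin, stood at -0.01 ± 0.23. In the p53 target list (camera adjusted p = 0.272, median -0.18), MDM2, the ubiquitin ligase of p53, was at 0.72 ± 0.21 and the secreted stress factor GDF15 at -0.86 ± 0.28. In the hypoxia and glycolysis list (camera adjusted p = 0.983, median 0.02), NDRG1 was at -1.40 ± 0.29 and passed adjusted over the list alone (limma adjusted p = 0.0310). The AP-1 and immediate early list (camera adjusted p = 0.159) had a median of -0.18, with EGR2, a zinc finger transcription factor, at -1.51 ± 0.51. In the Wnt target list (camera adjusted p = 0.902, median 0.05), CCND1, cyclin D1, was at -0.78 ± 0.32. For some lists the signs of median and mean differed: the mean was -0.02 for epithelial genes, -0.08 for hypoxia and glycolysis, -0.03 for Wnt targets and -0.15 for NF-kB and inflammatory genes.

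Markers of other cell types did not pass. Fibroblast markers had a camera adjusted p of 0.0786 and a median of -0.56, endothelial markers 0.122 and -0.85, and leukocyte markers 0.122 and -0.75. Of the endothelial markers 5 of 9 were tested, and of the leukocyte markers 7 of 13. Some members of these lists had few counts, so the medians are uncertain. In the SW620 control and knockdown libraries 1 and 2, TEK stood at 4.9, 0 and 2.1 normalized counts, HBA1 at 1.0, 0 and 1.0 and FAP at 0, 0 and 4.1. Ribosomal protein genes had a camera adjusted p of 0.122 (median 0.16), extracellular matrix and adhesion genes 0.159 (-0.16), and G2/M and mitosis genes 0.246 (0.10). Oxidative phosphorylation genes had 0.258 (0.09), the unfolded protein response and ATF4 targets 0.315 (-0.19), and apoptosis regulators 0.793 (0). Cholesterol biosynthesis genes had 0.829 (-0.16), NF-kB and inflammatory genes 0.829 (0.01), interferon-stimulated genes 0.829 (0), and enterocyte and colon differentiation genes 0.829 (-0.20). Over all lists, TEAD4, HIST1H1C and NDRG1 were the only members that passed adjusted over the list alone in limma.

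**Figure D2:**
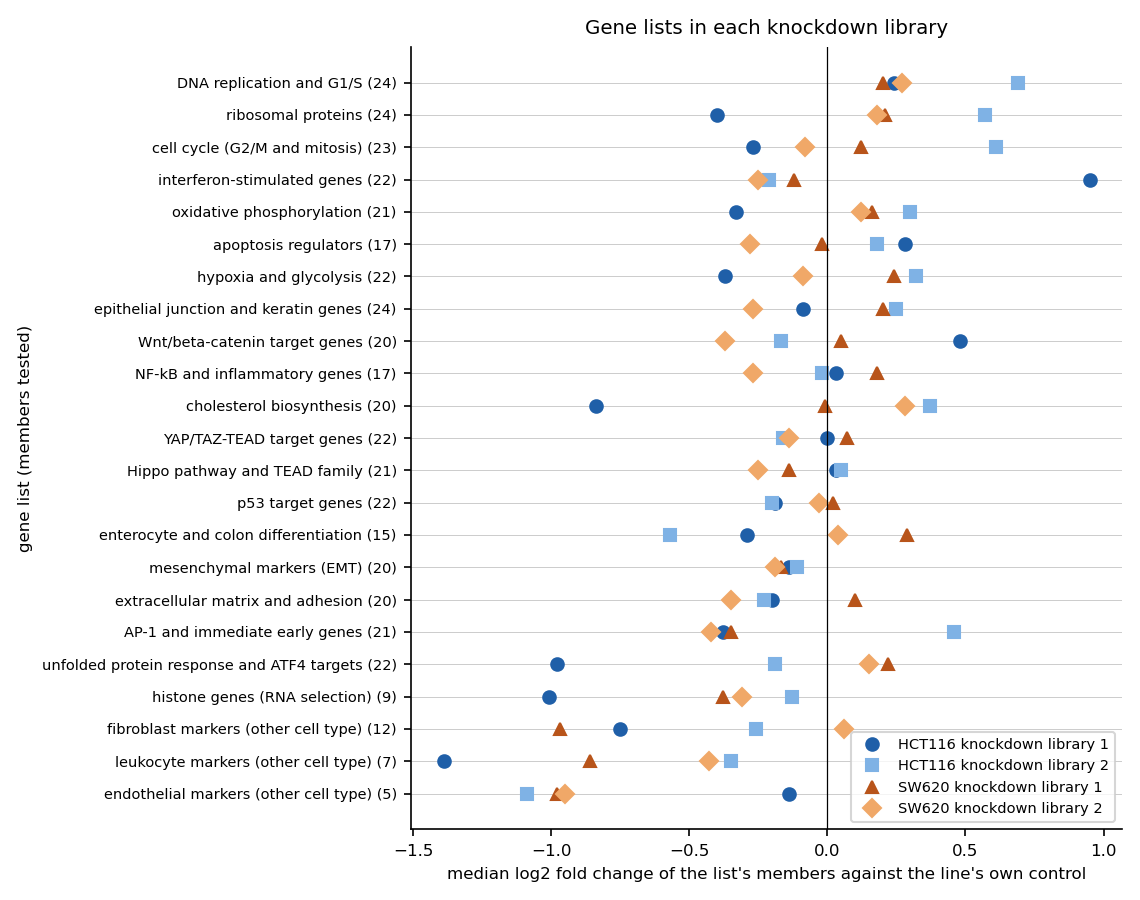
Median log2 fold change of each gene list against the line's own control (x axis) in each of the 4 knockdown libraries, with the number of members tested beside the list name and 1 marker shape per library. The DNA replication and G1/S list lies above 0 in all 4 libraries (0.24, 0.69, 0.20 and 0.27), and the unfolded protein response list lies at -0.98 and -0.19 in HCT116 and at 0.22 and 0.15 in SW620.

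In HCT116 alone, CTGF, a textbook YAP/TAZ-TEAD target, had the smallest p-value. It stood at 2736 normalized counts in the control and at 228 and 227 in the knockdown libraries, a log2 fold change of -3.58 ± 0.35 (SE). CYR61, at 4296 in the control, stood at 752 and 2063 (-1.79 ± 0.63), and ANKRD1, at 216, stood at 53.7 and 47.2 (-2.08 ± 0.75). SIRT1, a protein deacetylase, and TET3, which oxidises 5-methylcytosine, were higher, at 1.73 ± 0.26 and 1.79 ± 0.28. SIRT1 went from 228 to 777 and 742 normalized counts and TET3 from 261 to 976 and 842.

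SLC4A8 had a log2 fold change of -3.06 ± 0.44 in HCT116 and TEAD4 one of -2.36 ± 0.35. With limma, 0 genes passed in HCT116 and the smallest adjusted p was 0.828, while 1036 genes had an unadjusted p under 0.05 (537 higher, 499 lower) against 937 by chance. edgeR called 0 genes and DESeq2 19, of which 8 were higher and 11 lower. On simulated data for HCT116, DESeq2 made 7 calls among unchanged genes and recovered 74% of 4-fold and 96% of 8-fold changes. DESeq2 gave CTGF an adjusted p of 2.8e-11, SLC4A8 0.00139, TEAD4 0.00444 and TET3 0.0397. The authors' deposited table called 6 genes, all lower: CTGF (adjusted p = 7.66e-07) and, each at an adjusted p of 0.0222, SLC4A8, PLAG1, GOLGA8IP, SLC2A3 and KIF5C. GOLGA8IP belongs to a family of near-identical copies, so its count is uncertain. Of these, SLC2A3, a neuronal-type glucose transporter, went from 1096 to 205 and 122 normalized counts. KIF5C, a kinesin heavy chain, went from 1577 to 300.3 and 238, and PLAG1, a zinc finger transcription factor, from 267 to 14.6 and 30.0.

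The YAP/TAZ-TEAD target list had 13 of 22 members lower in HCT116 and 8 higher, with a median of -0.34 and a camera adjusted p of 0.218. Of its members, 4 had an unadjusted p under 0.05, all lower: CTGF, CYR61, ANKRD1 and CCDC80 (-2.15 ± 0.69). Only CTGF passed adjusted over the list alone (limma adjusted p = 0.00322). TEAD4 passed adjusted over its list (0.0213), and HIST1H1C, at -1.58 ± 0.34, did not (0.0505, limma).

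DNA replication and G1/S genes were higher as a group in HCT116, with 21 of 24 members positive, a median of 0.45 and a camera adjusted p of 1.4e-05 (0.883 with an estimated correlation). MCM5 stood at 1.14 ± 0.28, GINS1 at 0.97 ± 0.28, MCM4 at 0.86 ± 0.28 and MCM3 at 0.83 ± 0.28. Unfolded protein response and ATF4 target genes were lower as a group, with 16 of 22 members negative, a median of -0.65 and a camera adjusted p of 0.0268 (0.883 with an estimated correlation). PDIA4, a protein disulphide isomerase, stood at -1.33 ± 0.35 and the co-chaperone DNAJC3 at -0.74 ± 0.26. HSPA5, the endoplasmic reticulum chaperone BiP, stood at 130042 normalized counts in the control and at 15285 and 72816 in the knockdown libraries (-1.96 ± 0.93). HSP90B1, the chaperone GRP94, was at -1.03 ± 0.43. In knockdown library 1, where the list's median was -0.98, that of the histone list was -1.01, against -0.19 and -0.13 in knockdown library 2.

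Among the other members of fixed lists with an unadjusted p under 0.05 in HCT116 were NF2 (1.16 ± 0.32), MDM2 (0.99 ± 0.28), FSCN1 (1.1 ± 0.30) and PKP3, a desmosomal plakophilin (0.95 ± 0.28). OASL and IFIH1, interferon-induced genes, were at 1.44 ± 0.45 and 1.49 ± 0.54. NDRG1 stood at -1.24 ± 0.46 and the tight junction gene CLDN1 at -2.55 ± 0.78, from 35.6 to 6.4 and 4.3 normalized counts. TEAD1 (-0.56 ± 0.58), TEAD2 (0.65 ± 0.72), TEAD3 (0.32 ± 0.34), YAP1 (0.86 ± 0.70), WWTR1 (0.59 ± 0.49), VIM (0.25 ± 0.66) and CDH1 (-0.21 ± 0.34) did not pass, and none had an unadjusted p under 0.05. The camera adjusted p of the DNA replication list was 0.0659 without HCT116 knockdown library 2 (median 0.24) and 4.1e-07 without HCT116 knockdown library 1 (0.69). That of the unfolded protein response list was 0.0844 without HCT116 knockdown library 1 (median -0.19), 0.00293 without HCT116 knockdown library 2 (-0.98), 0.240 and 0.259 without SW620 knockdown library 1 or 2 (median -0.65 in each), 0.143 in the 3 HCT116 libraries alone, 0.0706 with libraries centred on their median and 0.263 with no filter on low values.

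In SW620 alone, CTGF and CYR61 were not lower with knockdown. CTGF stood at 84.9 normalized counts in the control and at 96.9 and 115 in the knockdown libraries (log2 fold change 0.31 ± 0.35, SE), and CYR61 at 63.5, 112 and 120.0 (0.86 ± 0.63). ANKRD1 had 0 reads in the control and 1.0 normalized count in 1 knockdown library, which is too few to compare. The YAP/TAZ-TEAD target list did not pass in SW620 (camera adjusted p = 0.749), with 13 of 22 members lower and a median of -0.23. Among the genes with the smallest p-values, CRIP1, a small LIM domain protein, went from 179 to 37.6 and 30.8 (-2.36 ± 0.37). PLA2G2A, a secreted phospholipase, went from 33.2 to 1.0 and 0, and CYP26B1, which degrades retinoic acid, from 15.6 to 1.0 and 1.0.

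OR51B2, an olfactory receptor gene, had 0 reads in the SW620 control and 18.8 and 22.6 normalized counts in the knockdown libraries. These are 41 reads against 0, and the lower 95% counting bound of the ratio was 5.48. The ratio of knockdown to control was 0.0152 for PLA2G2A (95% counting interval 3.73e-04 to 0.0904) and 0.0644 for CYP26B1 (0.00719 to 0.274), and these bounds and intervals cover counting error only. With limma, 0 genes passed in SW620 and the smallest adjusted p was 1, while 272 genes had an unadjusted p under 0.05 (98 higher, 174 lower) against 937 by chance. The spread was shared with the HCT116 knockdown pair, which differed more (chi-square per degree of freedom 109.9 against 30.9). The SW620 standard errors can therefore be too large and this count too low. edgeR called 0 genes and DESeq2 called 7, of which 3 were higher and 4 lower, with TEAD4 (-2.18 ± 0.35 in limma) at an adjusted p of 0.0497 and CRIP1 at 0.0258. On simulated data for SW620, DESeq2 made 6 calls among unchanged genes and recovered 66% of 4-fold and 94% of 8-fold changes. The authors' deposited table called 3 genes, all lower: TEAD4, SLC5A3, a myo-inositol transporter (adjusted p = 2.81e-04), and EMP1, an epithelial membrane protein (0.00648). TEAD4 passed adjusted over its list alone (limma adjusted p = 0.0302).

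In SW620, 3 gene lists passed with camera. DNA replication and G1/S genes were higher, with 22 of 24 members positive, a median of 0.22 and a camera adjusted p of 0.00571 (0.824 with an estimated correlation). GINS1 stood at 0.40 ± 0.28, MCM4 at 0.39 ± 0.28 and GINS2 at 0.37 ± 0.29. AP-1 and immediate early genes were lower, with 17 of 21 members negative, a median of -0.32 and a camera adjusted p of 0.00571 (0.824 with an estimated correlation). The EGR transcription factors EGR2 (-2.05 ± 0.70), EGR3 (-1.62 ± 0.62) and EGR1 (-0.96 ± 0.69) and the ETS factor ETV5 (-0.45 ± 0.25) were among them. Ribosomal protein genes were higher, with 24 of 24 members positive, a median of 0.20 and a camera adjusted p of 0.0472 (0.888 with an estimated correlation). RPL5 stood at 0.26 ± 0.41 and RPS3 at 0.33 ± 0.53, and ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain.

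CDH17, an intestinal cadherin, went from 51.7 to 185 and 206 normalized counts in SW620 (1.90 ± 0.58). HIST1H1C was at -1.41 ± 0.34, NDRG1 at -1.56 ± 0.46, GDF15 at -1.20 ± 0.41 and the integrin gene ITGA3 at -0.90 ± 0.30. TEAD1 (-0.46 ± 0.58), TEAD2 (-1.0 ± 0.72), TEAD3 (-0.13 ± 0.34), YAP1 (-0.66 ± 0.70), WWTR1 (-1.20 ± 0.49), VIM (-1.24 ± 0.66) and CDH1 (0.19 ± 0.34) did not pass. Without SW620 knockdown library 1 or 2, the camera adjusted p was 0.0873 or 0.0695 for the DNA replication list (median 0.27 or 0.20), 0.0873 or 0.173 for the AP-1 list (-0.42 or -0.35) and 0.404 or 0.155 for the ribosomal list (0.18 or 0.21). With no filter on low values it was 0.0895 for the AP-1 list and 0.185 for the ribosomal list, which also had 0.103 with libraries centred on their median, 0.0756 with a pseudocount of 0.1 and 0.0946 with the trend on GC content and length removed. Quantile normalization left the ribosomal list a median of 0.08 (camera adjusted p = 0.0211).

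The test of the difference between the lines, SW620 minus HCT116, put CTGF first. Its log2 fold change was -3.58 in HCT116 and 0.31 in SW620, a difference of 3.89 ± 0.49 (SE). CYR61 had a difference of 2.64 ± 0.90 and ANKRD1 one of 2.59 ± 1.06, the latter on almost no reads in SW620. HMOX1, heme oxygenase, went from 173 to 794 and 648 normalized counts in HCT116 and from 84.9 to 48.4 and 36.9 in SW620, a difference of -3.04 ± 0.59. TEAD4 itself differed by 0.17 ± 0.49.

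With limma, 0 genes passed the test of the difference and the smallest adjusted p was 1, while 423 genes had an unadjusted p under 0.05 against 937 by chance. edgeR called 0 genes, and DESeq2 called 1, CTGF, with an adjusted p of 7.1e-05. CTGF also passed adjusted over the list alone, the YAP/TAZ-TEAD targets (limma adjusted p = 0.0113). That list as a whole did not pass the test of the difference (camera adjusted p = 0.386). Its difference was positive for 11 members and negative for 11, with a median of 0.04. The ratio of knockdown to control reads of CTGF was 0.0833 in HCT116 (95% counting interval 0.0753 to 0.0920, 463 against 2691 reads) and 1.24 in SW620 (0.965 to 1.62, 210 against 87 reads). Of the other genes with the smallest p-values, TM4SF18, LTF and C1QTNF8 rested on few reads. TM4SF18 went from 1.0 to 20 and 18.2 normalized counts in HCT116 and from 3.9 to 1.0 and 0 in SW620. LTF, lactoferrin, stood at 3.0, 0 and 0 in HCT116 and at 0, 5.9 and 5.1 in SW620, and C1QTNF8 at 0, 3.6 and 6.4 and at 3.9, 0 and 0.

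Unfolded protein response and ATF4 target genes differed as a group, lower in HCT116 and not in SW620, with 18 of 22 members having a positive difference, a median of 0.92 and a camera adjusted p of 0.00141 (0.975 with an estimated correlation). PDIA4 differed by 1.45 ± 0.50, DNAJC3 by 1.06 ± 0.37, the amino acid transporter subunit SLC3A2 by 1.15 ± 0.53 and PDIA6 by 0.93 ± 0.43. Enterocyte and colon differentiation genes had a median difference of 1.11, with 10 of 15 members positive and a camera adjusted p of 0.0458 (0.975 with an estimated correlation). CDH17 differed by 2.2 ± 0.82, while SLC26A3, AQP8 and LGALS4 rested on 8.1 normalized counts or fewer in HCT116. DNA replication and G1/S genes were higher by less in SW620, with 19 of 24 members having a negative difference, a median of -0.28 and a camera adjusted p of 0.0487 (0.975 with an estimated correlation). MCM5 differed by -0.94 ± 0.39, CCNE1, cyclin E, by -1.0 ± 0.59 and GINS1 by -0.57 ± 0.39.

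OASL differed by -1.94 ± 0.63, WWC1, the Hippo scaffold KIBRA, by 0.89 ± 0.34, and LYZ, lysozyme, which had 0 to 3.6 normalized counts in HCT116, by -2.85 ± 0.94. The difference was 0.10 ± 0.83 for TEAD1, -1.65 ± 1.02 for TEAD2, -0.45 ± 0.48 for TEAD3, -1.52 ± 0.98 for YAP1, -1.79 ± 0.70 for WWTR1, -1.50 ± 0.93 for VIM and 0.41 ± 0.49 for CDH1. The camera adjusted p of the unfolded protein response difference was 0.102 without SW620 knockdown library 1 (median 0.90) and 0.126 with no filter on low values (0.92), and the median was 0.42 without HCT116 knockdown library 1 (0.00423) and 1.41 without HCT116 knockdown library 2 (2.4e-04). That of the enterocyte difference was 0.0860 without HCT116 knockdown library 1 (median 0.75), 0.165 without HCT116 knockdown library 2 (0.85) and 0.229 without SW620 knockdown library 1 (0.63), and without SW620 knockdown library 2 the median was 0.54 (0.0453). It was 0.610 with no filter on low values (median 0.56), 0.157 with a mean of at least 5 normalized counts (0.73), 0.0987 with quantile normalization (0.84) and 0.0513 with a pseudocount of 0.1 (1.12). That of the DNA replication difference was 0.749 without HCT116 knockdown library 2 (median -0.25), 0.102 without SW620 knockdown library 1 (-0.18), 0.0582 without SW620 knockdown library 2 (-0.39) and 2.0e-04 without HCT116 knockdown library 1 (-0.42). It also missed the threshold with quantile normalization (0.0987), libraries centred on their median (0.132), no filter (0.1), a mean of at least 5 normalized counts (0.0943), a pseudocount of 0.1 (0.0513) and the trend on GC content and length removed (0.0520), with medians from -0.28 to -0.19.

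The lines shared more of the genes that were lower than independent lists would. Among genes with an unadjusted limma p under 0.05, 19 were lower in both lines, against 4.6 by chance (Fisher's exact test, one-sided, p = 2.1e-07), and TEAD4, FLNC, HIST1H1C, SLC4A8, TGM2 and NDRG1 were among them. Of the genes that were higher, 6 were shared, against 2.8 by chance (p = 0.0625, same exact test). The single-line tests borrow their spread from all 6 libraries, so a gene of small spread can reach that p in both lines without a shared effect. Fisher's exact test also takes genes as independent, which they are not, so its p-values here can be too small. With each line's 3 libraries fitted alone, a test chosen after the results were seen, 10 genes were shared lower, against 2.3 by chance (exact p = 1.0e-04), and 5 higher, against 0.9 (exact p = 0.00236). At adjusted p under 0.05 in limma, 0 genes were shared, since 0 were called in each line.

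**Figure D3:**
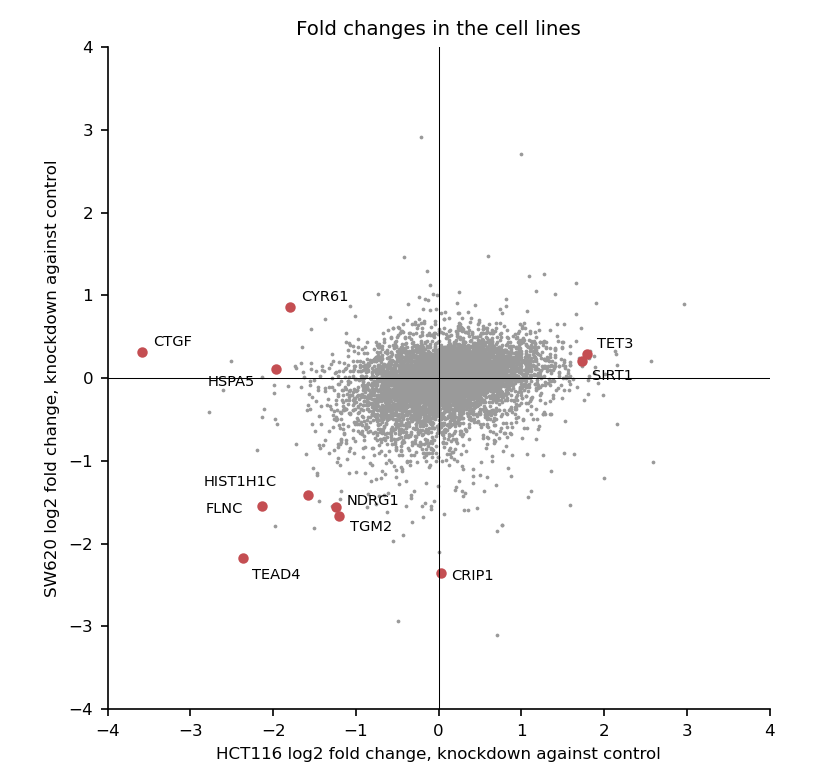
Log2 fold change of knockdown against control in HCT116 (x axis) and in SW620 (y axis) for the 9372 genes at or above the median level, 1 grey point per gene, with named genes in red. TEAD4, FLNC, HIST1H1C, NDRG1 and TGM2 lie low on both axes, and CTGF lies at -3.58 in HCT116 and 0.31 in SW620.

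Across 9372 genes at or above the median level, the mean log2 fold changes of the lines, which share no library, had a Pearson r of 0.266 and a Spearman rho of 0.284. Genes are not independent replicates, so these values describe the libraries only. Between knockdown libraries of the same line, which share a control, r was 0.380 in HCT116 (covariance 0.135) and 0.427 in SW620 (0.0524). Unchanged libraries simulated against a shared control gave an r of 0.501 and a covariance of 0.115. That r follows by arithmetic when all libraries have equal spread, and the covariance used a spread pooled over both lines. The simulated values therefore cannot tell whether knockdown libraries of a line agreed more or less than unchanged ones would. The SD of the log2 fold changes was 0.72 and 0.49 in the HCT116 knockdown libraries and 0.29 and 0.42 in the SW620 ones.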

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

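The tests on CTGF, on HCT116 knockdown library 1 and on GC content and length in this part were chosen after the results were seen. The random lists were also not among the tests fixed before the data were examined. The results given here are effects of TEAD4 knockdown that differed between HCT116 and SW620 by the test of the difference itself.

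CTGF was lower with knockdown in HCT116 and not in SW620, with a difference of 3.89 (limma adjusted p = 0.0113 adjusted over the YAP/TAZ-TEAD list alone, 1 over all genes). Low depth in SW620 is argued against as the reason that no fall was seen there, since the lower counting bound of the SW620 ratio of knockdown to control, 0.965, lies far above the HCT116 ratio of 0.0833. CTGF also stood at 84.9 normalized counts in the SW620 control and at 2736 in the HCT116 control, in tables normalized separately. A candidate explanation, untested here, is that CTGF depends on TEAD4 in HCT116 and on other factors in SW620. With 1 control library per line, a control that stands apart by itself stays open.

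The difference in the unfolded protein response and ATF4 list had a camera adjusted p of 0.00141 and a median of 0.92. It did not pass with an estimated correlation (camera adjusted p = 0.975), a setting that could hardly call a list here. A trend on GC content and length is argued against as the whole cause, since removing it left a camera adjusted p of 0.00202 and a median of 0.90. HCT116 knockdown library 1 stays open as the source of much of it, since without that library, when all spread comes from the SW620 pair, the median went from 0.92 to 0.42 (camera adjusted p = 0.00423), against 1.41 without HCT116 knockdown library 2, and the lower list in HCT116 alone was lost (0.0844). Without SW620 knockdown library 1 the camera adjusted p was 0.102 with a median of 0.90, so the size of the difference was kept and the call was not. Culture state at harvest, the hairpins and an effect of TEAD4 in HCT116 stay open and were not tested.

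DNA replication and G1/S genes were higher with knockdown in both lines (camera adjusted p = 2.9e-07, 0.646 with an estimated correlation), and the difference between the lines had a median of -0.28 (camera adjusted p = 0.0487, 0.975 with an estimated correlation). The median of HCT116 knockdown library 1, 0.24, lay between those of the SW620 libraries, 0.20 and 0.27, and without HCT116 knockdown library 2 the difference had a camera adjusted p of 0.749 (median -0.25), without SW620 knockdown library 1 one of 0.102 (-0.18), without SW620 knockdown library 2 one of 0.0582 (-0.39) and without HCT116 knockdown library 1 one of 2.0e-04 (-0.42). For the higher list in both lines, removing the trend on GC content and length left a camera adjusted p of 1.8e-06 (0.0520 for the difference, median -0.24), and the largest on leaving out 1 library, the HCT116 control, was 0.00467 (median 0.22, against 0.34 with all libraries). Of 10000 random lists matched on abundance, 0 had a median as high, so a shift of all genes of like abundance is argued against. A change in the cycling of the knockdown cultures stays open beside an effect of TEAD4, since the G2/M and mitosis list (camera adjusted p = 0.246, median 0.10) had medians of -0.27 and 0.61 in the HCT116 and 0.12 and -0.08 in the SW620 knockdown libraries, where the DNA replication list had 0.24, 0.69, 0.20 and 0.27.

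The enterocyte and colon differentiation list differed with a camera adjusted p of 0.0458 (0.975 with an estimated correlation) and a median of 1.11, and with 0.157 and 0.73 among genes with a mean of at least 5 normalized counts. The camera adjusted p was 0.0860 without HCT116 knockdown library 1 (median 0.75), 0.165 without HCT116 knockdown library 2 (0.85) and 0.229 without SW620 knockdown library 1 (0.63), and without SW620 knockdown library 2 the median was 0.54 (0.0453). It was 0.610 with no filter on low values (median 0.56), 0.0987 with quantile normalization and 0.0513 with a pseudocount of 0.1.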

How the results depend on the processing

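The edgeR, DESeq2, GC and length, and replicate block tests, the overlap of each line's libraries alone at unadjusted p, and all alternatives for the gene lists other than fry and the estimated correlation, were chosen after the results were seen. With limma, 0 genes passed in the 4 comparisons under each alternative except 1. That was HCT116 with no filter on low values, where 545 passed (12 higher, 533 lower). Of these, 510 had a mean under 1 normalized count, 505 had no spread within either knockdown pair and 483 had reads in the HCT116 control only. Most of these calls thus rest on genes the filter removes. The others were tested with the filter too, where 0 genes passed. For HCT116 and for SW620, limma recovered 0% of simulated changes at every fold, and recovery for the difference was not simulated. A count of 0 repeated over alternatives in those comparisons therefore does not show that changes were absent. For both lines it does not show this either, since TEAD4 itself missed the threshold in limma. edgeR called 0 in each comparison, and DESeq2 called 15 in both lines, 19 in HCT116, 7 in SW620 and 1 for the difference. The cause of these unlike counts was not tested. TEAD4 kept its direction throughout, from -2.36 to -2.14 in both lines, -2.42 to -2.21 in HCT116 and -2.28 to -2.07 in SW620, and its adjusted p over all genes ranged from 5.8e-14 to 1, 0.00444 to 0.999 and 0.0497 to 1. The column number of the knockdown libraries as a replicate block gave 0 calls in limma in each comparison (756, 785, 252 and 306 genes at an unadjusted p under 0.05, for both lines, HCT116, SW620 and the difference), and crossed numbers also gave 0 (1089, 1263, 371 and 476). Crossing was tried because the deviations of same-numbered libraries had r = -0.207 across genes. The planned block on the letters A and B was not run, since the columns carry no letters.

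Of gene lists, 2 passed camera in both lines, 2 in HCT116, 3 in SW620 and 3 for the difference. With fry and with an estimated correlation 0 passed in each, and neither setting was run on simulated lists. In HCT116, 1 passed with libraries centred on their median, 1 with no filter and 1 with its 3 libraries alone. In SW620, 1 passed with no filter, 6 with a mean of at least 5 normalized counts and 7 with its 3 libraries alone. For the difference, 0 passed with no filter, 1 with a mean of at least 5 and 1 with a pseudocount of 0.1. Leaving out 1 library gave 2 to 6 lists in both lines (6 without either HCT116 knockdown library), 1 to 6 in HCT116 (6 without its knockdown library 1, 1 without either SW620 knockdown library), 0 to 5 in SW620 (0 without its knockdown library 1) and 0 to 6 for the difference (0 without SW620 knockdown library 1). For a single line, leaving out a knockdown library of the other line keeps its log2 fold changes by construction. Those moves can come only from the estimate of the spread and the set of genes tested. The cause of the other moves was not tested. The median log2 fold change of all genes lay within 0.066 of 0 under each scaling. Overlap of the lines went from 0 genes at adjusted p under 0.05 to 25 at unadjusted p under 0.05; with each line's libraries alone it was 0 at adjusted p and 15 at unadjusted p.

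Among named genes, 1544 values kept direction and side of the threshold, 26 passed only under the alternative and 1 reversed, CDH1 in both lines (0.06 with the GC and length trend removed). Leaving out 1 library kept 595 and turned 23. Without a control, the effect in both lines comes from the other line alone by construction, so ranges are wide: CTGF -3.58 to 0.31, ANKRD1 -2.08 to 0.51, CYR61 -1.79 to 0.86, CDH1 -0.21 to 0.19, VIM -1.24 to 0.25, TEAD3 -0.13 to 0.32, TEAD2 -1.0 to 0.65, WWTR1 -1.20 to 0.59 and YAP1 -0.66 to 0.86. VIM in HCT116 stood at -0.02 without knockdown library 2 and 0.52 without 1. CDH1 in SW620 stood at -0.13 without knockdown library 1 and 0.51 without 2, and YAP1 at -1.50 and 0.18. The TEAD1 difference was -0.42 without HCT116 knockdown library 1 and 0.61 without 2. The libraries' depth limits the low genes: with 0 to 4 reads in a control (PLA2G2A in HCT116, LTF, C1QTNF8, TM4SF18), only a bound or a wide interval can be given.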

Other observations

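The genes of this part were chosen after their values were seen, and the values are given with no explanation. In SW620, 4 genes whose products act in secretory vesicles had higher values in both knockdown libraries, with the highest in knockdown library 2; they were picked by value, and no list of such genes was tested. SYP, synaptophysin, stood at 102.5 normalized counts in the control and at 389 and 1802 in the knockdown libraries. CPLX2, complexin 2, stood at 92.8, 285 and 2485, SCG3, secretogranin 3, at 23.4, 97.9 and 867.5, and CHGB, chromogranin B, at 484, 774 and 2747. DESeq2 gave adjusted p-values of 0.0258 for SYP and CPLX2 and 0.0384 for SCG3, and 1 for CHGB, while limma gave 1 for all of them. In the same library, YAP1 stood at 2970 normalized counts, against 8427 in the control and 9567 in knockdown library 1. VIM stood at 1014, 3942 and 2725 and TEAD2 at 115.9, 417 and 373 in that order of libraries. DHRS3, a retinoid-reducing enzyme, went from 216 to 38.5 and 18.5 in SW620 (DESeq2 adjusted p = 0.0378), and EMP1 from 650.3 to 144 and 39.0 (0.0258).

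In HCT116, MACC1, a regulator of metastasis in colon cancer, stood at 279.6 normalized counts in the control and at 1056 and 1435 in the knockdown libraries (DESeq2 adjusted p = 0.00285). FGF19, an endocrine fibroblast growth factor, stood at 168, 819 and 469 (0.0487 in DESeq2). The HCT116 knockdown libraries stood apart on several gene lists. Median log2 fold changes against the control, in knockdown libraries 1 and 2, were 0.95 and -0.21 for interferon-stimulated genes, -0.84 and 0.37 for cholesterol biosynthesis, and -0.40 and 0.57 for ribosomal proteins. They were -0.27 and 0.61 for G2/M and mitosis genes, -0.38 and 0.46 for AP-1 and immediate early genes, and 0.48 and -0.17 for Wnt targets. TEAD4 stood at 19.2% and 19.3% of the control in these libraries.

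Between knockdown libraries of different lines, which share no library, the correlation of log2 fold changes across 9372 genes was 0.349 for HCT116 knockdown library 2 with SW620 knockdown library 1, 0.199 for HCT116 knockdown library 1 with SW620 knockdown library 2, 0.118 for the libraries numbered 1 and 0.137 for those numbered 2. Genes are not independent replicates, and the labels do not tie the libraries of the lines to each other.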
